A study of Mus musculus with 15 samples.

How the data were processed

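RNA of small-intestinal epithelial cells from wild-type BALB/c mice was measured on 15 Affymetrix arrays, 3 for untreated controls and 3 for each of 4 lengths of RANKL treatment. RANKL is the TNF-family cytokine that binds the receptor RANK, and it was given intraperitoneally as a GST fusion protein for up to 4 days. No group given GST or vehicle alone is among the samples. Effects of the injections or of GST therefore cannot be told apart from those of RANKL in any comparison with control. Per the labels the mice were 10 weeks of age, the epithelium was loosened with 30 mM EDTA for 10 min, and the target was biotinylated with the WT Terminal Labeling Kit. The deposited values are a linear intensity for each of 28853 probe sets on each array, from 25.95 to 24106.7. The genome build named by the submitters is mm9, and the summarisation, background correction and normalization are not given in the sources used here. No coordinates are given, since the gene table used here follows another build.

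The deposited intensities were taken to log2 with no offset (pseudocount 0). A limit of 0.1 on the range of the array medians had been fixed before the data were examined, together with the tests, the gene lists, most of the other settings tried and the rule for naming genes. The log2 medians ran from 7.20 to 7.38, a range of 0.18, so the columns were quantile normalized. Of the probe sets, 21789 carried 1 gene symbol, 1621 carried several and 5443 were not listed in the annotation. Each of 19938 genes was represented by the probe set with the highest mean over the 15 arrays, a choice that mattered for the 999 genes with over 1 probe set. No filter on dim genes was applied.

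Differences were tested with limma 3.58.1 in R 4.3.3. A single linear model with 1 mean per group was fitted to all 15 arrays without a block, which left 10 residual degrees of freedom and 3.49 prior degrees of freedom. The contrasts were each RANKL day against control and each day against the day before. A moderated F test covered the 4 contrasts against control. P-values were adjusted by the Benjamini-Hochberg method over all genes within each contrast, and a gene was called at an adjusted p under 0.05. Counts were also taken with an absolute log2 change of 1 or more. All tests were two-sided.

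Gene lists numbered 33 and held 798 symbols, of which 718 were matched to a measured gene. Each list was tested on each day with camera from limma, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01. The 132 list tests were adjusted together. Beside it stand camera with a correlation estimated from the data, fry, the number of members called over all genes, and the number called when adjusted over the list alone. Differences between days were tested by the same methods over 99 list tests.

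Genes were named by a rule. For each day against control it took the 12 largest rises and the 8 largest falls among called genes whose 3 RANKL arrays lay on 1 side of all 3 control arrays, without unnamed clones. For each day against the day before it took the 4 largest changes in each direction, for the F test the 6 smallest p-values, and for each list described up to 4 called members with the largest change. Gp2, Spib, Tnfaip2, Ccl9, Ccl20, Tnfrsf11a, Relb and Nfkb2 were always included. A gene could be left out where it repeated the account of another day. The lists described were chosen after the values were seen. They are those whose call on a day held without each array in turn, 36 of 61 calls, and the other 25 calls are given only as this count.

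The alternatives tried were other scalings, an offset of 16, leaving out the dimmest 40% of genes, other treatments of multiple probe sets, a trended and robust prior, weights per array, the replicate number as a block, unmoderated statistics, fits of only the groups compared, and leaving out each array in turn. The method was tested on simulated data with 19938 genes, 50 of them changed at each of several sizes. It recovered 56 to 70% of genes changed by 0.5 on the log2 scale and 94 to 96% of those changed by 1, and 3.6 to 6.9% of its calls were false. The simulated noise was independent between genes and had the same SD on every array. Real genes are correlated and the real arrays differ in spread, so these rates need not hold for them. The number of arrays per group limits the precision. Detection flags and scan dates were not used here. No source says whether the 3 arrays of a group came from separate mice, so the p-values measure the spread between these samples.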

Results

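The series measured gene expression in epithelial cells detached from the small intestine of mice, without RANKL and after 1, 2, 3 or 4 days of RANKL. Each of the 5 groups had 3 arrays. The median intensity per array ran from 147 to 167. The highest median belonged to RANKL day 1 replicate 2, whose deposited log2 values also had the narrowest interquartile range, 1.95 against 2.26 to 2.55 on the other arrays. The first principal component of the normalized values held 23.3% of the variance and the second component 21.9%. RANKL is known to drive the formation of M cells, the epithelial cells that carry particles from the gut lumen to lymphoid tissue, and the comparisons with control ask which genes move on each day of treatment.

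After 1 day of RANKL the largest rise was in H2-M2 (probe set 10450880), a nonclassical MHC class I gene, by 4.78 ± 0.26 on the log2 scale (SE, n = 3 arrays per group; 27.5-fold). Spib, the Ets-family transcription factor needed for M cell development, rose by 4.57 ± 0.20 (23.7-fold), from a mean log2 intensity of 6.65 ± 0.15 (SD, n = 3) in controls to 11.22 ± 0.32. The M cell receptor gene Gp2 was not called on this day, with a change of -0.02 ± 0.34 (adjusted p = 0.992). Its values on day 1 (5.8 to 6.2) and in controls (5.9 to 6.2) lay little above the 4.88 to 5.50 read by Y chromosome genes. Those genes mark the background here, as described under day 4. A small change of Gp2 could therefore be missed on day 1, and its later folds may be understated. Rises of 2.60 ± 0.20 for Anxa5, which encodes a phosphatidylserine-binding protein, and 2.51 ± 0.24 for Nox1, the catalytic subunit of an epithelial NADPH oxidase, were also called. Ccl20, which encodes the chemokine ligand of CCR6, rose 5.18-fold. Serpina10 (2.58), Adgrd1 (2.50), Itih5 (2.37), Mfge8 (2.23), Ctsh (2.16), Ncf4 (2.05) and Cd44 (2.04) made up the other largest log2 rises.

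On day 1, 16 of the 23 measured M cell markers rose and none fell, with a mean log2 change of 1.21 over the list. Adjusted over the list alone, 18 were higher and 1 lower. Some markers on this list are known from RANKL-treated epithelium, possibly from these very arrays, so the list is not independent evidence. Cxcl16, a transmembrane chemokine, rose by 1.95 on the log2 scale, Ccl9, another chemokine, by 1.56 ± 0.17, and Tnfaip2, linked to membrane protrusions, by 1.45 ± 0.22. The camera adjusted p of the list was 3.05e-31, and it was 0.00889 with an estimated correlation. Of 23 genes of the NF-kB pathway and its targets, 14 rose and none fell, against 16 higher when adjusted over the list alone. Nfkb2, the precursor of the p52 subunit, rose by 1.63 ± 0.08 (3.11-fold), Icam1, an adhesion molecule, by 1.84, and Relb, the partner of p52, by 0.43 ± 0.07 (adjusted p = 0.00355). The call of Relb was lost with the values as deposited (0.0635), with median centring (0.187) and in a fit of the 2 groups alone (0.0866). Tnfrsf11a, which encodes the receptor RANK itself, rose 1.71-fold (adjusted p = 0.000884). The NF-kB list had an adjusted p of 9.54e-22, and 0.00344 with an estimated correlation.

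On day 1 Cyp2c65, a cytochrome P450 gene, fell by 2.24 ± 0.40 on the log2 scale, and Slc40a1, which encodes the iron exporter ferroportin, fell by 2.10 ± 0.37 (4.29-fold lower; adjusted p = 0.0056). Scd1, a fatty acid desaturase, fell by 1.96, Akr1c14 by 1.86, the mucosal chemokine gene Ccl28 by 1.75 (not called in a fit of the 2 groups alone, 0.0866), the cytokine gene Il18 by 1.69 and the gasdermin gene Gsdmc2 by 1.53 ± 0.11. Slc5a4a also fell by 1.71 (adjusted p = 0.0376), but its call ended without RANKL day 1 replicate 1 (0.125), RANKL day 1 replicate 3 (0.0943), RANKL day 2 replicate 2 (0.0544), RANKL day 3 replicate 3 (0.0534), control replicate 2 (0.128) or control replicate 3 (0.147). It also ended with the values as deposited (0.0511), median centring (0.0568), a trended and robust prior (0.055), an ordinary t (0.112) and the 2 groups alone (0.0552). Of 33 genes of xenobiotic and glutathione metabolism, 10 fell and none rose, against 15 lower and 2 higher when adjusted over the list alone. Cyp2c65 and the carboxylesterase gene Ces2a (-1.48) changed most. The list had an adjusted p of 3.72e-05, and its call was lost with an estimated correlation (adjusted p = 0.443 with an estimated correlation).

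By limma, 785 of 19938 genes were called on day 1, 398 higher and 387 lower, and 112 of them changed by a log2 value of 1 or more (69 higher, 43 lower). A fit of the 2 groups alone called 269. The main fit shares 1 spread per gene over all groups, although the day 1 arrays deviated more from their group mean than later ones. Their root mean square deviations were 0.1891, 0.2209 and 0.1444, against 0.0971 to 0.138 on days 2 to 4. The counts therefore do not rank the days by size of response. After centring each array on its median in place of quantile normalization, 480 genes were called and 37.3% of them were higher, against 50.7%. Without control replicate 3 the count was 445. Without RANKL day 1 replicate 2, which stood apart on the first principal component, it was 1005 (645 higher, 360 lower), and 624 of the 785 stayed called in the same direction.

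**Figure D1:**
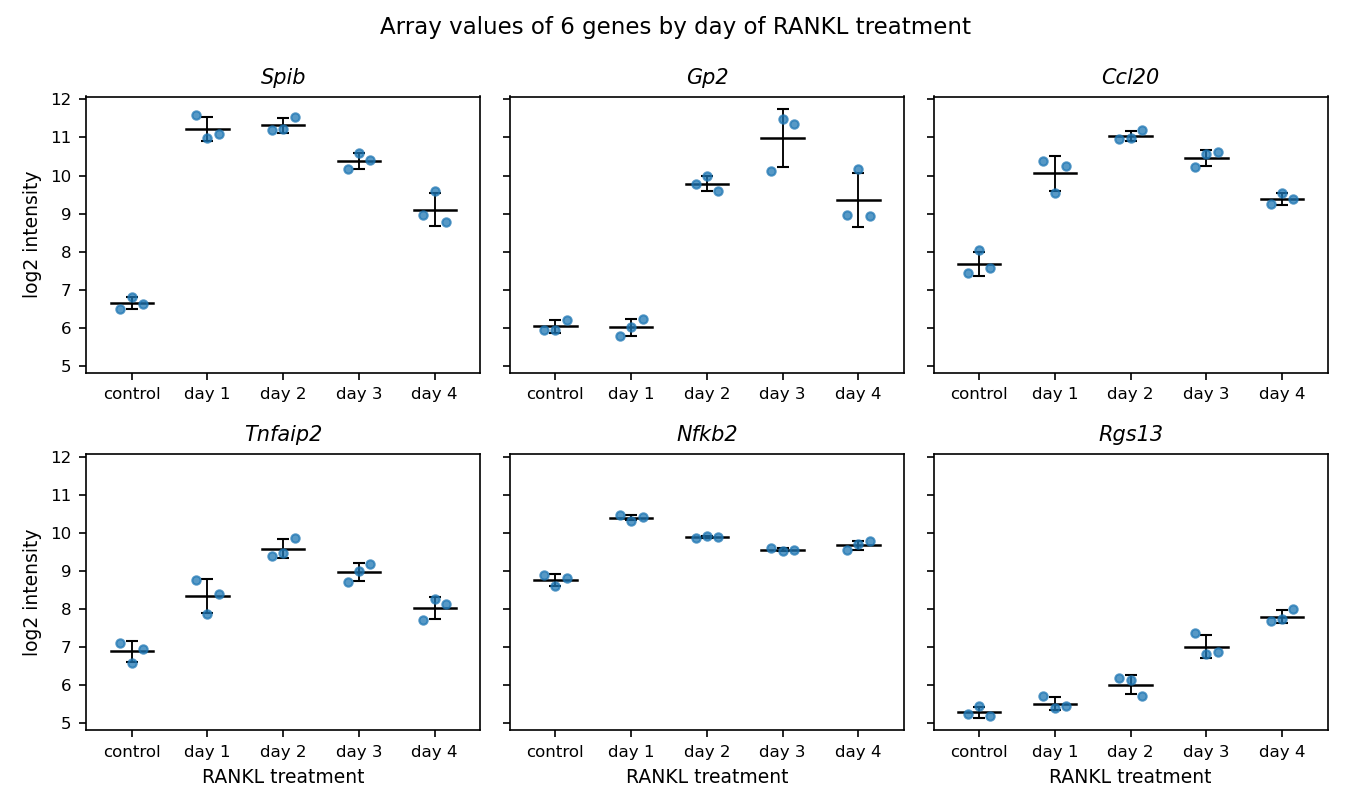
Log2 intensity of Spib, Gp2, Ccl20, Tnfaip2, Nfkb2 and Rgs13 on each array (points), by group along the horizontal axis, with the mean (line) and SD of the 3 arrays. Gp2 stayed at its control level on day 1 and reached its highest mean, 10.99, on day 3, while the mean of Spib was highest on day 2 at 11.31.

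On day 2 Gp2, whose protein takes up bacteria at the surface of M cells, rose by 3.75 ± 0.34 on the log2 scale (SE, n = 3 arrays per group; 13.4-fold), to a mean of 9.79 ± 0.21 (SD) against 6.04 ± 0.16 in controls. Spib stood 25.4-fold above control and H2-M2 15.8-fold. Anxa5 rose by 3.55 ± 0.20, Ccl20 by 3.36 ± 0.20, Nox1 by 3.29 ± 0.24 and Tnfaip2 by 2.70 ± 0.22. Lcn2, which encodes the siderophore-binding protein lipocalin 2, rose 6.84-fold, the sugar transporter gene Slc2a6 rose 6.83-fold, Fabp5, a fatty acid binding protein gene, rose 5.64-fold and Wfdc17 rose 5.30-fold. Tnfrsf11a stayed higher, at 1.58-fold (adjusted p = 0.00402), whereas Relb was not called (0.18, adjusted p = 0.304).

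M cell markers were called higher in 21 of 23 on day 2, over all genes and also when adjusted over the list alone, where 1 was lower. The mean log2 change of the list was 1.77, and with an estimated correlation its adjusted p was 0.00344. In the NF-kB list 13 of 23 rose (15 when adjusted over the list alone), with Ccl20, Icam1 (1.46) and Nfkb2 (1.13) ahead, and an adjusted p of 0.00344 with an estimated correlation. Of 27 chemokine genes, 7 rose and none fell, and 7 were also higher when adjusted over the list alone. Ccl9 and Cxcl16 are also on the M cell list and Ccl20 on the NF-kB list, so this list is not separate from those. Ccl20, Ccl9 (2.33), Cxcl9 (1.89) and Cxcl16 (1.57) changed most, and the call of Cxcl9 was lost without RANKL day 2 replicate 1 (0.104), RANKL day 2 replicate 2 (0.0556), control replicate 1 (0.0545) or control replicate 3 (0.0982). The median change of the chemokine list was 0.04 and its mean 0.44, and its call (adjusted p = 2.43e-05) was lost with an estimated correlation (adjusted p = 0.0833 with an estimated correlation). Of 22 antimicrobial and acute-phase genes, 2 rose, Lcn2 and the hepcidin gene Hamp (2.18), and 1, Reg4 (-1.19), fell, against 8 higher and 2 lower when adjusted over the list alone. That list had an adjusted p of 0.000327, lost with an estimated correlation (adjusted p = 0.454 with an estimated correlation). The call of Reg4 (adjusted p = 0.0472) was lost without RANKL day 1 replicate 3 (0.0631), RANKL day 2 replicate 2 (0.159), RANKL day 2 replicate 3 (0.151), RANKL day 3 replicate 3 (0.0675), RANKL day 4 replicate 1 (0.0633), RANKL day 4 replicate 3 (0.0521), control replicate 1 (0.171), control replicate 2 (0.101) or control replicate 3 (0.0999), with median centring (0.127), with the values as deposited (0.071), with an offset of 16 (0.0542), with a trended and robust prior (0.0619) and with an ordinary t (0.144).

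Scd1 remained low on day 2, having fallen by 1.86 on the log2 scale, as did Gsdmc2, which fell by 1.36. Ifnlr1, the receptor gene for lambda interferons, fell by 1.44 ± 0.14 (adjusted p = 3.02e-05). Xenobiotic and glutathione genes fell in 8 of 33 and rose in 1 (11 lower and 1 higher when adjusted over the list alone), with an adjusted p of 0.000149 that was lost with an estimated correlation (adjusted p = 0.455 with an estimated correlation). Cyp2c65 fell by 2.06, a call that ended without RANKL day 2 replicate 2 (0.0724) or control replicate 3 (0.0653), and Cyp3a25 by 1.44, a call that ended without RANKL day 2 replicate 1 (0.05). Cyp2c55 fell by 1.36 and Gclc, which encodes an enzyme of glutathione synthesis, rose by 1.10, calls that ended without control replicate 3 (0.0513 and 0.0526). Slc40a1 fell by 1.82 with an adjusted p of 0.0173, which passed 0.05 without RANKL day 2 replicate 1 (0.0938), RANKL day 2 replicate 2 (0.0886), control replicate 1 (0.0618), control replicate 2 (0.0532) or control replicate 3 (0.0631). The ectonucleotidase gene Nt5e fell by 1.52, but was not called without RANKL day 2 replicate 1 (0.0586), RANKL day 2 replicate 2 (0.064), RANKL day 2 replicate 3 (0.0713), control replicate 2 (0.0511) or control replicate 3 (0.101). The lipase gene Pnliprp2 fell by 1.40, but was not called without control replicate 1 (0.0768) or control replicate 3 (0.0622).

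In all, 513 genes were called on day 2, 303 higher (59.1%) and 210 lower, of which 116 changed by a log2 value of 1 or more (91 higher, 25 lower). The count was 294 without RANKL day 2 replicate 1, 288 without RANKL day 2 replicate 2 and 283 without control replicate 3. With median centring it was 311.

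On day 3 Gp2 reached its largest difference from control, 4.95 ± 0.34 on the log2 scale (SE, n = 3 arrays per group; 30.9-fold), and Spib stood 13.4-fold above control. Lcn2 rose by 3.14 ± 0.38 and Hamp, which encodes the iron-regulating peptide hepcidin, by 2.45 ± 0.20 (5.46-fold). The control values of Hamp, 5.43 to 5.90, reached down to the background, so its rise may be understated. H2-M2 (3.30), Anxa5 (3.16), Ccl20 (2.78), Nox1 (2.63), Itih5 (2.35), the surface protein gene Ly6d (2.29), Wfdc17 (2.27), Mfge8 (2.17), Ccl9 (2.09) and Tnfaip2 (2.08) were among the other log2 rises. Tnfrsf11a (0.42, adjusted p = 0.0532) and Relb (-0.13, adjusted p = 0.437) were not called.

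M cell markers rose in 19 of 23 on day 3 (21 when adjusted over the list alone), with a mean log2 change of 1.48 and an adjusted p of 0.00548 with an estimated correlation. NF-kB genes rose in 6 of 23 (11 when adjusted over the list alone), led by Ccl20, Icam1 (1.15) and Nfkb2 (0.80), with an adjusted p of 0.0454 with an estimated correlation. Tuft cell markers, genes of the chemosensory cells of the epithelium, rose in 5 of 21 (6 when adjusted over the list alone). Rgs13, a regulator of G protein signalling whose control level lay at background, rose by at least 1.72, the cation channel gene Trpm5 by 0.88, the kinase gene Dclk1 by 0.57 and the prostaglandin synthase gene Hpgds by 0.54. The call of Trpm5 was lost without RANKL day 3 replicate 3 (0.0935), control replicate 1 (0.0676) or control replicate 2 (0.0659), and that of Hpgds without RANKL day 3 replicate 1 (0.0561), RANKL day 3 replicate 2 (0.0644), RANKL day 3 replicate 3 (0.0583) or control replicate 1 (0.0556). The tuft list had an adjusted p of 0.000245, lost with an estimated correlation (adjusted p = 0.443 with an estimated correlation). Intestinal stem cell markers rose in 2 of 22 (9 when adjusted over the list alone), namely the water channel gene Aqp4, at 1.28 (adjusted p = 3.48e-05), and the RNA-binding protein gene Msi1, at 0.83, whose call was lost without RANKL day 3 replicate 3 (0.0606). The stem cell list had an adjusted p of 1.9e-08, lost with an estimated correlation (adjusted p = 0.443 with an estimated correlation).

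Falls on day 3 included Scd1, by 1.90 on the log2 scale, Cyp3a25 by 1.60 ± 0.26, Gsdmc2 by 1.46, Ifnlr1 by 1.45 and the amino acid transporter gene Slc6a20b by 1.34 ± 0.11. For another 3 falls the call was lost without some single array. Cyp2c65 fell by 2.00, a call lost without RANKL day 3 replicate 1 (0.0546), RANKL day 3 replicate 3 (0.089) or control replicate 3 (0.0762). Slc40a1 fell by 1.77, a call lost without RANKL day 3 replicate 2 (0.0864), RANKL day 3 replicate 3 (0.0647), control replicate 1 (0.0644), control replicate 2 (0.0659) or control replicate 3 (0.0702). The phospholipase gene Pla2g4c fell by 1.41, a call lost without RANKL day 3 replicate 2 (0.0548), RANKL day 3 replicate 3 (0.0625), control replicate 1 (0.0525) or control replicate 2 (0.0506).

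Day 3 had 590 called genes, 342 higher (58%) and 248 lower, and 94 of them changed by a log2 value of 1 or more (71 higher, 23 lower). The count was 1189 without RANKL day 1 replicate 2, 316 without RANKL day 3 replicate 2, 236 without RANKL day 3 replicate 3, 384 without control replicate 1, 355 without control replicate 2 and 270 without control replicate 3. It was 378 with the values as deposited and 257 with median centring.

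On day 4 the M cell genes remained above control by smaller margins, with Gp2 at 10.0-fold and Spib at 5.49-fold, while H2-M2 stood at 15.2-fold. Rgs13 rose by 2.51 ± 0.16 on the log2 scale (SE, n = 3 arrays per group), from a mean of 5.30 ± 0.14 (SD) to 7.80 ± 0.17. Its control level lay within the 4.88 to 5.50 read by Y chromosome genes, which mark the background here because Xist read 11.93 or more on every array, so this difference is a lower bound. Itih5 (2.33), Nox1 (2.20), Anxa5 (2.05), Mfge8 (1.82), Ctsh (1.76), the glutathione transferase gene Gsta3 (1.73), Ccl20 (1.71) and Ccl9 (1.26) were also called higher. Nfkb2 rose 1.88-fold, whereas Tnfrsf11a (0.44, adjusted p = 0.0888) and Relb (0.02, adjusted p = 0.959) were not called. Tnfaip2 rose 2.21-fold (adjusted p = 0.0255), a call lost without RANKL day 4 replicate 2 (0.14), RANKL day 4 replicate 3 (0.094), control replicate 2 (0.141) or control replicate 3 (0.0685). The steroid dehydrogenase gene Hsd17b6 rose 5.99-fold (adjusted p = 0.00839), a call lost without RANKL day 4 replicate 2 (0.0508).

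Of 25 enteroendocrine markers 6 rose and none fell on day 4, against 13 higher when adjusted over the list alone, with an adjusted p of 1.65e-12, and 0.0189 with an estimated correlation. The hormone gene Cck rose by 1.25 (2.37-fold; adjusted p = 0.000305), the proglucagon gene Gcg by 1.03, and the transcription factor genes Rfx6 by 0.78 and Neurod1 by 0.77. The call of Gcg was lost with median centring (0.055), with an ordinary t (0.0764) and without RANKL day 4 replicate 2 (0.0658), RANKL day 4 replicate 3 (0.0684), control replicate 2 (0.0924) or control replicate 3 (0.0624), and that of Neurod1 without RANKL day 4 replicate 1 (0.0714), RANKL day 4 replicate 2 (0.107), control replicate 1 (0.0905) or control replicate 3 (0.0536). Neurod1 was also not called with an ordinary t (0.0764) or in a fit of the 2 groups alone (0.052). Of 21 tuft cell markers 7 rose and none fell, against 10 higher when adjusted over the list alone. Beside Rgs13, Trpm5 rose by 1.16, Dclk1 by 1.02 and Pou2f3, a transcription factor gene of the tuft lineage, by 0.69. The call of Pou2f3 was lost without RANKL day 4 replicate 2 (0.0833), RANKL day 4 replicate 3 (0.076), control replicate 2 (0.0928) or control replicate 3 (0.0739). The tuft list had an adjusted p of 1.71e-10, lost with an estimated correlation (adjusted p = 0.0833 with an estimated correlation). Both lists moved together with a lower mean of 24 markers of T cells and intraepithelial lymphocytes (-0.26), none of which was called over all genes and 1 of which was lower when adjusted over the list alone. The largest changes there were -0.64 for Gzmb and -0.62 for Gzma, and the list's adjusted p of 3.7e-07 was lost with an estimated correlation (adjusted p = 0.443 with an estimated correlation). M cell markers rose in 13 of 23 (20 when adjusted over the list alone; adjusted p = 0.00889 with an estimated correlation), and NF-kB genes in 5 of 23 (12 when adjusted over the list alone; adjusted p = 0.0152 with an estimated correlation).

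Falls were few on day 4. Gsdmc2 fell by 1.23 ± 0.11 on the log2 scale, Ifnlr1 by 1.09 ± 0.14 and Tgfbi, which encodes an extracellular matrix protein, by 0.90 ± 0.12. The complement gene C2 fell by 1.04, but was not called without control replicate 2 (0.0544). The metal transporter gene Slc30a10 fell by 1.13, but was not called without RANKL day 4 replicate 1 (0.0727), RANKL day 4 replicate 2 (0.0858), control replicate 2 (0.0987) or control replicate 3 (0.0756). Slc40a1 fell by 1.77 (adjusted p = 0.0417), Pla2g4c by 1.30 and the carbonic anhydrase gene Car3 by 1.00, and these calls were lost without any 1 of 9, 7 and 7 arrays. For Slc40a1 they were RANKL day 1 replicate 1 (0.052), RANKL day 2 replicate 1 (0.0536), RANKL day 2 replicate 2 (0.0612), RANKL day 3 replicate 3 (0.0615), RANKL day 4 replicate 1 (0.192), RANKL day 4 replicate 2 (0.209), control replicate 1 (0.141), control replicate 2 (0.154) and control replicate 3 (0.102). For Pla2g4c they were RANKL day 2 replicate 3 (0.0503), RANKL day 3 replicate 3 (0.0568), RANKL day 4 replicate 1 (0.17), RANKL day 4 replicate 2 (0.0947), RANKL day 4 replicate 3 (0.09), control replicate 1 (0.174) and control replicate 2 (0.173). For Car3 they were RANKL day 2 replicate 2 (0.0504), RANKL day 3 replicate 3 (0.0504), RANKL day 4 replicate 1 (0.134), RANKL day 4 replicate 2 (0.108), RANKL day 4 replicate 3 (0.081), control replicate 1 (0.122) and control replicate 3 (0.0638).

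Day 4 had 181 called genes, 163 higher (90.1%) and 18 lower, and 54 of them changed by a log2 value of 1 or more (47 higher, 7 lower). The count was 338 without RANKL day 1 replicate 2, 113 without RANKL day 4 replicate 1, 94 without RANKL day 4 replicate 2, 120 without control replicate 1 and 96 without control replicate 2.

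**Figure D2:**
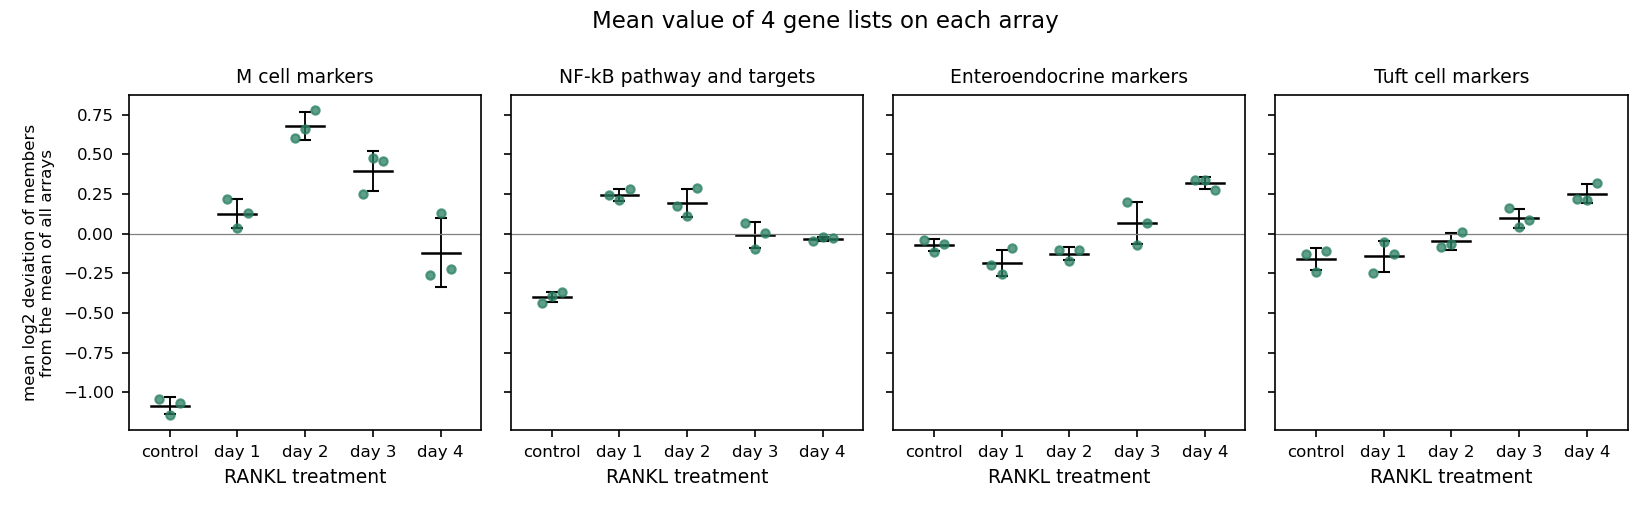
Mean log2 deviation of the measured members of the M cell, NF-kB, enteroendocrine and tuft cell lists from their mean over all arrays, for each array (points), with the group mean (line) and SD of 3 arrays. The mean change against control of the M cell list was 1.77 on day 2 and 0.97 on day 4, and that of the tuft cell list was 0.41 on day 4.

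Genes moving at any time were tested across the 4 days together. Spib had the smallest p of this test (adjusted p = 2.37e-07), and Clca3a2, Icam1, Nfkb2, H2-M2 and Anxa5 followed. Clca3a2, a member of the calcium-activated chloride channel regulator family, rose by 1.96, 2.17, 1.77 and 1.65 on days 1 to 4 on the log2 scale. The limma F test called 718 genes. For 161 genes with a higher largest change that change fell on day 1, for 97 on day 2, for 61 on day 3 and for 85 on day 4. For genes with a lower largest change the numbers were 153, 93, 67 and 1. Noisier arrays favour their day in this count. RANKL day 1 replicates 1 and 2 deviated most from their group mean (root mean square 0.1891 and 0.2209). The numbers alone therefore do not show an early peak of the response. Called on every day were 93 genes higher and 14 lower. Days 2 and 3 shared 200 higher and 125 lower calls, where 5.20 and 2.61 would be shared if the calls were independent. These expected numbers take no account of the 3 controls that all days share. Across genes, which are not independent replicates, the log2 changes of days 2 and 3 had a correlation of 0.812, against 0.502 in data simulated with shared controls and no effects, whereas those of days 1 and 4 had 0.486 against 0.498. The covariance of the changes of days 1 and 4 was 0.0223 against 0.0095 in the simulated data. Days 1 and 4 shared 122 calls in the same direction, against 0 in each simulation. With no effects in the simulated data hardly any gene could be called, so shared calls near 0 were fixed in advance. That comparison does not show how many of the 122 come from the shared controls. The simulated noise was independent between genes and had the same spread in all groups, which the real arrays do not have. The simulated correlations are therefore not an exact reference. Without control replicate 3 the F test called 430 genes.

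**Figure D3:**
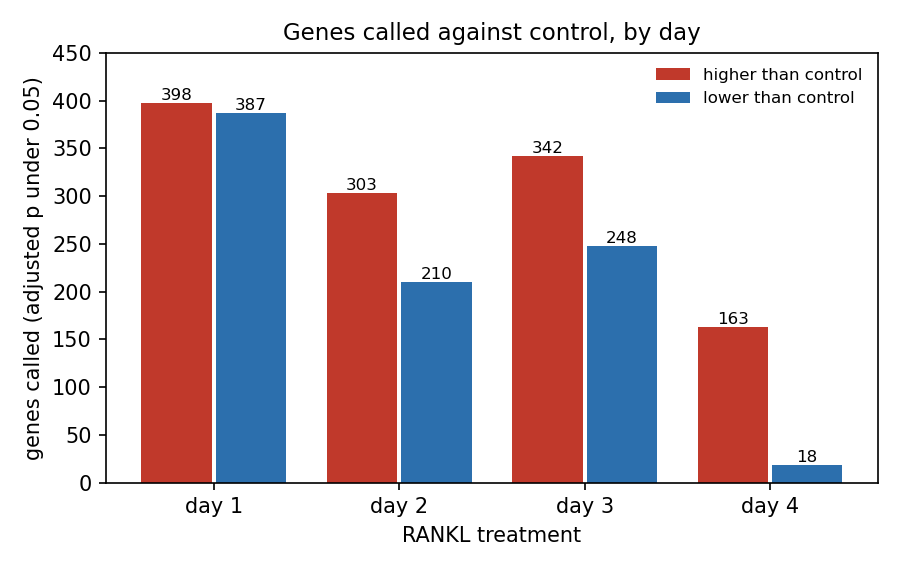
Number of genes called higher (red) and lower (blue) than control at an adjusted p under 0.05 on each day, with 3 arrays per group and bars from 0. Higher calls numbered 398, 303, 342 and 163 on days 1 to 4, and lower calls 387, 210, 248 and 18. All days share 1 estimate of the spread per gene, so the bars do not rank the days by size of response.

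From day 1 to day 2 Gp2 rose by 3.77 ± 0.34 on the log2 scale (SE, n = 3 arrays per group; 13.6-fold; adjusted p = 0.000335), Hamp by 1.99 (adjusted p = 0.000659), and Tagln2, which encodes an actin-binding protein, fell by 0.65 (adjusted p = 0.00304). These 3 calls held without each array in turn, but that of Tagln2 was lost with median centring (0.0532) and in a fit of the 2 groups alone (0.117). Cxcl9, an interferon-induced chemokine gene, rose by 2.19 and Wfdc17 by 1.99, while Mal, which encodes a protein of membrane traffic, fell by 1.16, the calcineurin regulator gene Rcan1 by 0.79 and the cell cycle kinase gene Cdk6 by 0.77. With median centring the calls of Cxcl9 (0.0849), Mal (0.109), Rcan1 (0.0966) and Cdk6 (0.203) were lost. With the values as deposited those of Cxcl9 (0.0565), Mal (0.0628) and Cdk6 (0.0959) were lost. The call of Cxcl9 was lost without RANKL day 1 replicate 2 (0.138), RANKL day 1 replicate 3 (0.141), RANKL day 2 replicate 1 (0.187), RANKL day 2 replicate 2 (0.119), RANKL day 2 replicate 3 (0.112), RANKL day 3 replicate 2 (0.0549), RANKL day 3 replicate 3 (0.0658), RANKL day 4 replicate 1 (0.0633) or control replicate 1 (0.0641). The call of Wfdc17 was lost without RANKL day 1 replicate 3 (0.0587), RANKL day 2 replicate 1 (0.0532) or RANKL day 2 replicate 3 (0.0723). Mal was not called without RANKL day 1 replicate 2 (0.0664), RANKL day 1 replicate 3 (0.105), RANKL day 2 replicate 1 (0.132), RANKL day 2 replicate 2 (0.119), RANKL day 3 replicate 2 (0.0525) or control replicate 3 (0.0544). Rcan1 was not called without RANKL day 1 replicate 2 (0.0656), RANKL day 1 replicate 3 (0.0761), RANKL day 2 replicate 1 (0.106) or RANKL day 2 replicate 2 (0.0893). Cdk6 was not called without RANKL day 1 replicate 1 (0.0965), RANKL day 1 replicate 2 (0.0656), RANKL day 1 replicate 3 (0.0912), RANKL day 2 replicate 1 (0.0532) or RANKL day 2 replicate 3 (0.0723).

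In all 40 genes were called from day 1 to day 2, 29 higher (72.5%) and 11 lower. With median centring 19 were called and 94.7% of them were higher, and with the values as deposited 17. The count was 25 without RANKL day 1 replicate 1, 11 without RANKL day 1 replicate 2, 9 without RANKL day 1 replicate 3, 7 without RANKL day 2 replicate 1, 17 without RANKL day 2 replicate 2, 14 without RANKL day 2 replicate 3, 23 without RANKL day 3 replicate 2, 26 without RANKL day 4 replicate 1 and 25 without control replicate 3.

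Between day 2 and day 3 limma called 0 genes, with 961 genes at an unadjusted p under 0.05. From day 3 to day 4 Hamp fell by 1.96 ± 0.20 on the log2 scale (SE, n = 3 arrays per group; adjusted p = 0.00412), a call that held without each array in turn. The other 2 of the 3 called genes were Wfdc18, a whey acidic protein family gene, which fell by 1.51, and Plekhs1, which fell by 1.06 (adjusted p = 0.0085 for each). Wfdc18 was not called without RANKL day 4 replicate 1 (0.0765), and Plekhs1 was not called without RANKL day 3 replicate 3 (0.0835), RANKL day 4 replicate 1 (0.0765) or RANKL day 4 replicate 3 (0.0579). The count of 3 became 12 without RANKL day 1 replicate 2, 5 without RANKL day 2 replicate 3, 20 without RANKL day 3 replicate 1, 5 without RANKL day 3 replicate 2, 1 without RANKL day 4 replicate 1 and 15 without RANKL day 4 replicate 2. With the values as deposited or centred on the median it was 5. All 3 genes lost their call with unmoderated statistics (0.104) and in a fit of the 2 groups alone (0.224).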

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

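The tests of the scores, of the scalings and of Slc40a1 and RANKL day 1 replicate 2 below, and the counts of other splits, were chosen only after the results were seen.

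Markers of enteroendocrine and tuft cells were higher on day 4, with a mean score over both lists 0.40 above control (95% interval 0.295 to 0.507, 10 residual degrees of freedom). The scaling of the arrays is argued against, since the highest adjusted p of the 2 lists at the preset correlation, with the values as deposited or centred on the median, was 9.85e-08, although the tuft list lost its call with an estimated correlation (adjusted p = 0.0833 with an estimated correlation). More crypt material in the day 4 preparations stays open, because the score minus a crypt score rose by 0.34 with an interval of -0.077 to 0.757. A smaller share of lymphocytes raising the markers of all epithelial types alike also stays open, as the score minus an absorptive enterocyte score rose by 0.19 (-0.272 to 0.655) while T cell markers changed by -0.26 (-0.513 to -0.006). An effect of RANKL on these lineages remains a hypothesis from the same data.

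Slc40a1, which encodes ferroportin, was lower on all 4 days while Tfrc, the transferrin receptor gene, was called higher on days 2 to 4 (1.13, 1.63 and 1.16 on the log2 scale). Intestine sampled further towards the ileum in treated mice is argued against: other proximal markers minus ileal markers rose by 0.64 in the mean of the RANKL days (95% interval 0.143 to 1.144). The proximal score alone rose by 0.345 (-0.038 to 0.728), and the ileal score changed by -0.299 (-0.506 to -0.092). The proximal score included Hsd17b6, itself called higher on days 2 to 4 (2.30, 2.10 and 2.58). The difference was not computed without this gene, so the argument rests in part on it. Sampling shifted in the other direction, away from the ileum, stays open. That 1 array decides the fall of Slc40a1 is argued against as well, the smallest fall over 4 days and all left-out arrays being -1.41. The call itself was lost without some arrays on days 2 to 4, at adjusted p up to 0.209 without RANKL day 4 replicate 2, and that of Tfrc on day 4 without RANKL day 4 replicate 2 (0.0575) or control replicate 1 (0.0532). With an ordinary t Slc40a1 was not called on days 2 to 4 (0.0746, 0.077 and 0.154), nor Tfrc on day 4 (0.0618). Slc40a1 on day 4 was also not called with a trended and robust prior (0.0606) or in a fit of the 2 groups alone (0.0504). A regulation of these genes by RANKL remains a hypothesis. Of 7 other iron genes set beside them after the pattern was seen, Hamp (2.18 and 2.45) and Lcn2 (2.77 and 3.14) were called higher on days 2 and 3. Both had already been named from these same data, so they give no separate support. Slc11a2, Cybrd1, Heph, Fth1 and Ftl1 were not called on any day (lowest adjusted p 0.12).

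RANKL day 1 replicate 2 stood apart, at 35.95 on the first principal component against 17.15 for the next array, control replicate 1. A narrower spread of its intensities alone stays open. After quantile normalization its root mean square deviation from its group mean was 0.2209 and the next highest 0.1891. Quantile normalization stretches a narrow array together with its noise, so a high deviation afterwards cannot decide this. Without it 624 of the 785 genes of day 1 stayed called in the same direction, which argues against the view that it alone makes the calls. No biological explanation was tested, and a difference in cell composition or RNA quality stays open and untested.

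Genes that differed between RANKL days, by a test of that difference, numbered 40 from day 1 to day 2 and 3 from day 3 to day 4. From day 1 to day 2 the log2 differences were 3.77 for Gp2, 2.19 for Cxcl9, 1.99 for Wfdc17, 1.99 for Hamp, -1.16 for Mal, -0.79 for Rcan1, -0.77 for Cdk6 and -0.65 for Tagln2. The calls of Gp2, Hamp and Tagln2 held without each array, and that of Tagln2 was lost with median centring (0.0532). The other 5 calls were lost without single arrays, at adjusted p up to 0.187 for Cxcl9, 0.132 for Mal and 0.106 for Rcan1, each without RANKL day 2 replicate 1, 0.0965 for Cdk6 without RANKL day 1 replicate 1 and 0.0723 for Wfdc17 without RANKL day 2 replicate 3. Median centring also ended the calls of Cxcl9 (0.0849), Mal (0.109), Rcan1 (0.0966) and Cdk6 (0.203). From day 3 to day 4 the differences were -1.96 for Hamp, -1.51 for Wfdc18 (lost without RANKL day 4 replicate 1, 0.0765) and -1.06 for Plekhs1 (lost without RANKL day 3 replicate 3, 0.0835, RANKL day 4 replicate 1, 0.0765, or RANKL day 4 replicate 3, 0.0579).

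Lists also differed between days by such a test. The NF-kB list changed by -0.28 from day 1 to day 4 (adjusted p = 0.0377 with an estimated correlation), and lost this call without 7 arrays, namely control replicates 1 (0.0791), 2 (0.0842) and 3 (0.0704), RANKL day 1 replicates 1 (0.134) and 3 (0.107), RANKL day 2 replicate 1 (0.0505) and RANKL day 4 replicate 3 (0.0591). From day 2 to day 4 it changed by -0.22 (adjusted p = 0.0486 with an estimated correlation), lost without 11 arrays, namely control replicates 1 (0.0862), 2 (0.0944) and 3 (0.0727), RANKL day 1 replicates 1 (0.112), 2 (0.105) and 3 (0.101), RANKL day 2 replicate 1 (0.07), RANKL day 3 replicate 3 (0.0628) and RANKL day 4 replicates 1 (0.07), 2 (0.0512) and 3 (0.0634). The enteroendocrine list rose by 0.50 from day 1 to day 4 (adjusted p = 0.0299 with an estimated correlation), lost without control replicate 1 (0.0632), control replicate 3 (0.0504), RANKL day 1 replicate 1 (0.0946) or RANKL day 1 replicate 3 (0.0608). It rose by 0.44 from day 2 to day 4 (adjusted p = 0.0271 with an estimated correlation), lost without control replicate 1 (0.0604) or control replicate 3 (0.0503). The M cell list changed by -0.80 from day 2 to day 4 (adjusted p = 0.0271 with an estimated correlation), lost without control replicate 1 (0.0604) or control replicate 3 (0.0503). Outside the tested genes, 21 of 7064 probe sets without a single gene symbol were called by the F test, and probe set 10402390 was higher by 2.71, 2.80, 2.68 and 2.09 on days 1 to 4 on the log2 scale.

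The splits of 6 arrays into 3 and 3 number 10 and are too few for a share under 0.05. The real count and the highest of the other splits were 785 and 5 on day 1, 513 and 4 on day 2, 590 and 0 on day 3, 181 and 0 on day 4, 40 and 0 from day 1 to day 2, 0 and 0 from day 2 to day 3, and 3 and 1 from day 3 to day 4. As large a count came from 1 of the 10 splits, the real one, in each comparison but day 2 to day 3, where all 10 gave 0. Of 100 splits of the 15 arrays into 5 groups of 3, 1, the real one, gave as many genes by the F test (718, highest other 324). A random grouping of independent arrays would therefore give that count at a share under 0.05. No source says that the arrays are independent, so a mouse or run shared within a group stays open as its source.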

How the results depend on the processing

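The values as deposited, and leaving out RANKL day 1 replicate 2 together with control replicate 1, were added after the data were seen. The planned quantile normalization is the setting used throughout and gives no further value. Leaving out each array in turn, the counts ran from 445 to 1005 on day 1, 283 to 721 on day 2, 236 to 1189 on day 3, 94 to 338 on day 4, 7 to 53 from day 1 to day 2, 0 to 0 from day 2 to day 3, 1 to 20 from day 3 to day 4, 430 to 1037 for the F test and 53 to 67 list calls. Other counts that moved by over 1.5 times follow, and the cause was not tested. With the values as deposited they were 378 on day 3, 17 from day 1 to day 2 and 5 from day 3 to day 4, and with median centring 480, 311 and 257 on days 1 to 3, 19 and 5. A trended and robust prior gave 5 from day 3 to day 4. Array weights, whose fit did not fully converge, gave 1517, 930, 1322 and 307 on days 1 to 4, 711, 13 and 228 between days and 1423 by the F test. Unmoderated statistics gave 320, 324 and 107 on days 2 to 4, 7 and 0 between days (day 1 to 2, day 3 to 4) and 342 by the F test. Fits of the 2 groups alone gave 269 on day 1, 5 from day 1 to day 2 and 0 from day 3 to day 4. Without both arrays named above the counts were 18 from day 1 to day 2 and 10 from day 3 to day 4. With the replicate number as a block 69 genes were called from day 1 to day 2. Of 368 values of named genes, 8 lost their call with this block and 18 gained one. Among the losses were Tnfrsf19 on days 2 and 4 (0.0597 and 0.0623), Bgn (0.0519) and Plin2 (0.0585) on day 2, and Pdia6 on day 3 (0.0586). Same-number arrays of different groups had a median correlation of deviations of 0.144 against -0.075 for other pairs, and 12 of 15 arrays correlated best with their own number. Arrays of the same number thus deviated alike to some degree, but no pairing or batch is stated. The main fit has no block, so its p-values take no account of this. Of 61 list calls, 9 held with an estimated correlation and 15 with fry, and 36 held without each array. A single result reversed, Cell cycle genes list, RANKL day 1 against control (adjusted p = 0.969 without RANKL day 1 replicate 1, 0.0121 with all arrays, and 7.63e-08 at the lowest, without RANKL day 1 replicate 2 and control replicate 1). Of 368 values of named genes, 346 kept their direction and their side of the threshold with the values as deposited and 325 with median centring, and 0 reversed in either, while 79 lost their call with unmoderated statistics and 45 in fits of the 2 groups alone. Leaving out the dimmest 40% of genes, an offset of 16, and other choices of probe sets kept all counts of genes within 1.5 times. Signal near background limits what can be seen, since genes of the Y chromosome read 4.88 to 5.50 on the log2 scale on all arrays.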

Other observations

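The test on the M cell list from day 2 to day 4 was chosen only after the result was seen, and that on NADPH oxidase subunits was written before their values were looked at, while leaving out its dim members and the tests between days were chosen after.

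On day 1 1 of 31 oxidative phosphorylation genes fell, and 11 were lower when adjusted over the list alone, with a mean log2 change of -0.19 and an adjusted p of 8.51e-09, lost with an estimated correlation (adjusted p = 0.292 with an estimated correlation). The largest changes, -0.47 for Ndufb8 and -0.37 for Cox5a, were not called (adjusted p = 0.0726 and 0.0676), and the called member, Sdhb (-0.31, adjusted p = 0.0462), was looked up after the values were seen. Of 24 ribosomal protein genes none was called on that day and 2 were higher when adjusted over the list alone (mean 0.15, largest 0.33 for Rpl6; adjusted p = 2.12e-05, and adjusted p = 0.455 with an estimated correlation). Among 25 PPARa targets and genes of fatty acid oxidation 1 fell on day 1, Acadvl (-0.39, looked up after the values were seen), and 2 on day 2, Cpt1a (-0.64) and Plin2 (-0.53), against 6 and 11 lower when adjusted over the list alone (adjusted p = 0.522 and adjusted p = 0.443 with an estimated correlation). The call of Cpt1a was lost without control replicate 1 (0.0519) and that of Plin2 without any 1 of 10 arrays, at up to 0.204 without RANKL day 2 replicate 1, with median centring (0.178), with the values as deposited (0.101), with an offset of 16 (0.0505) and with an ordinary t (0.121). Cholesterol synthesis genes had a mean of -0.22 on day 4, with 0 of 19 called, 1 lower when adjusted over the list alone, and -0.76 for Tm7sf2 (adjusted p = 0.522 with an estimated correlation).

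Interferon-stimulated genes had a mean of -0.35 on day 1 and 0.28 on day 2, and all 26 were higher on day 2 than on day 1, by a mean of 0.62 (adjusted p = 0.164 with an estimated correlation). On day 1 Cxcl10, an interferon-induced chemokine gene, rose by 0.95 and Stat2, a transducer of interferon signals, fell by 0.71, and 1 was higher and 3 lower when adjusted over the list alone. The call of Cxcl10 was lost without control replicate 3 (0.0544), and that of Stat2 without RANKL day 1 replicate 1 (0.0614), RANKL day 1 replicate 3 (0.0617), control replicate 1 (0.0762) or control replicate 2 (0.0786), both with median centring (0.052 and 0.0587), Stat2 with an ordinary t (0.0698) and Cxcl10 in a fit of the 2 groups alone (0.0732). On day 2 Cxcl10 alone of the 26 was called (1.17; 1.33 for Ifit2, adjusted p = 0.131; 1 when adjusted over the list alone), and the list calls were lost with an estimated correlation (adjusted p = 0.713 with an estimated correlation on both days).

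Goblet cell markers fell in 2 of 17 on day 2, Bcas1 (-0.91) and the protease gene Capn9 (-0.55), and 4 were lower when adjusted over the list alone (adjusted p = 0.443 with an estimated correlation). The call of Bcas1 was lost without RANKL day 2 replicate 2 (0.064) or control replicate 3 (0.0636). On day 4 Capn9 and Creb3l4 rose by 0.53 each, and 3 were higher when adjusted over the list alone (adjusted p = 0.641 with an estimated correlation). These 2 calls were lost without any 1 of 5 and 6 arrays, at up to 0.125 for Capn9 without control replicate 2 and 0.108 for Creb3l4 without RANKL day 4 replicate 3. Intestinal stem cell markers rose in 3 of 22 on day 2, Aqp4 (1.39), Msi1 (0.75) and Tnfrsf19 (0.36), and in 2 on day 4, Aqp4 (0.78) and Tnfrsf19 (0.42), against 4 and 6 when adjusted over the list alone (adjusted p = 0.641 and adjusted p = 0.473 with an estimated correlation). Msi1 lost its call without 3 arrays, at up to 0.0675 without RANKL day 2 replicate 2, and Tnfrsf19 lost it without 13 arrays on day 2 (up to 0.229 without RANKL day 2 replicate 2) and 11 on day 4 (up to 0.191 without RANKL day 4 replicate 1). Cell cycle genes on day 3 had a mean of 0.38, with 2 of 39 called higher, Mcm2 (0.46) and Rrm2 (0.41), and 10 when adjusted over the list alone (adjusted p = 0.455 with an estimated correlation). Mcm2 lost its call without 5 arrays, at up to 0.087 without control replicate 3, and Rrm2 without 4, at up to 0.117 without RANKL day 3 replicate 3. With median centring Tnfrsf19 (0.0926 on day 2, 0.055 on day 4), Mcm2 (0.0938) and Rrm2 (0.0609) were not called, nor was Tnfrsf19 with the values as deposited (0.125 and 0.133). Tnfrsf19 and Mcm2 were also not called with an ordinary t (0.0767 and 0.0832 for Tnfrsf19 on days 2 and 4, 0.0588 for Mcm2) or in a fit of the 2 groups alone (0.155, 0.0617 and 0.0555). Msi1 on day 2 lost its call in the same 2 settings (0.0588 and 0.0921).

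Genes of the endoplasmic reticulum stress response rose in 3 of 22 on day 2, Hyou1 (0.58), Pdia4 (0.56) and Sdf2l1 (0.42), and in 2 on day 3, Pdia4 (0.63) and Pdia6 (0.56), against 8 and 9 when adjusted over the list alone (adjusted p = 0.422 and adjusted p = 0.455 with an estimated correlation). All these calls were lost without single arrays, on day 2 at up to 0.137 for Hyou1 and 0.105 for Pdia4, each without RANKL day 2 replicate 1, and 0.142 for Sdf2l1 without RANKL day 2 replicate 2, and on day 3 without RANKL day 3 replicate 3 at 0.0688 for Pdia4 and up to 0.176 for Pdia6. With the mean of all probe sets of a gene Pdia4 on day 3 was 0.38 higher and not called (0.0591). With median centring none of them was called, on day 2 at 0.123 for Hyou1, 0.156 for Pdia4 and 0.151 for Sdf2l1, and on day 3 at 0.0656 for Pdia4 and 0.146 for Pdia6. With the values as deposited Hyou1 (0.0596), Pdia4 (0.0713) and Sdf2l1 (0.0699) on day 2 and Pdia6 (0.0884) on day 3 were not called, and with an ordinary t these 4 were at 0.078, 0.0632, 0.0562 and 0.0994. Ileal markers fell in 3 of 14 on day 3, Amn (-0.83), Cubn (-0.78) and Osr2 (-0.56), and 6 were lower when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). These calls were lost without 4, 3 and 3 arrays, at up to 0.0994 for Amn and 0.064 for Osr2 without RANKL day 3 replicate 3 and 0.127 for Cubn without control replicate 3, with median centring for Cubn (0.0527) and Osr2 (0.103), with an ordinary t for Amn (0.0641) and Cubn (0.0928), and in a fit of the 2 groups alone for Cubn (0.117). On day 4 the list had a mean of -0.31 with 0 called and 1 lower when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). Of 15 proximal markers 3 rose on day 2, Hsd17b6 (2.30), Tfrc (1.13) and Apoa4 (0.71), and 1, Slc40a1, fell, against 4 and 1 when adjusted over the list alone (adjusted p = 0.443 with an estimated correlation). Apoa4 lost its call without 5 arrays, at up to 0.0707 without control replicate 1, and Slc40a1 without 5, at up to 0.0938 without RANKL day 2 replicate 1. Stromal, endothelial and muscle markers had a mean of -0.32 on day 2, and 1 of 22 fell, Bgn (-0.79; -0.89 for Acta2, adjusted p = 0.583), also when adjusted over the list alone (adjusted p = 0.583 with an estimated correlation), a call lost without 10 arrays, at up to 0.185 without control replicate 1, with median centring (0.0742), with the values as deposited (0.0645), with an offset of 16 (0.0505), with an ordinary t (0.134) and in a fit of the 2 groups alone (0.114). Antimicrobial and acute-phase genes on day 3 rose in 2 of 22, Lcn2 (3.14) and Hamp (2.45), and 4 when adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). Of the 33 lists 9 were not called on any day, among them the absorptive enterocyte markers and the genes of the osteoclast RANKL programme.

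A decline of the M cell programme after day 2 restates the lower values of day 4 and does not explain them. Gp2, a member of the M cell list, was highest on day 3. The list fell from day 2 to day 4 by 0.80 on the log2 scale, with an adjusted p of 0.0271 with an estimated correlation, which passed 0.05 without control replicate 1 (0.0604) or control replicate 3 (0.0503). The pattern was found and tested on the same data and remains a hypothesis.

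Nox1, Cyba, Ncf4 and Rac2, which encode parts of NADPH oxidases and were set together after their values were seen, were called higher on days 1 to 3, with Cyba at 1.31, 1.13 and 0.99 and Rac2 at 1.56, 2.10 and 1.35 on the log2 scale. A coordinated rise of the subunits would call at least 3 of 6 further subunits on day 2, and fewer than 1 in 4 called had been set beforehand as the limit against it. Of these 6, 1 was called, Ncf1, by 0.84 (adjusted p = 8.59e-05), and Noxo1 (0.38, adjusted p = 0.177), Noxa1 (0.17, adjusted p = 0.826) and Cybb (0.20, adjusted p = 0.716) were not. By that limit 1 of 6 argues against a coordinated rise of all 6 on day 2. The result rests on Nox3 and Nox4, which were among the dimmest 40% of genes. Without them, a choice made afterwards, it was 1 of 4, which meets neither limit. A rise of the 4 brighter subunits together stays open.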
